A study of Mus musculus with 8 samples.

How the data were processed

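Gene expression was measured by RNA-seq in 8 samples of left ventricle from male C57BL6 mice, 4 labelled Mst1-TG and 4 labelled WT. Per the labels' protocols, RNA was extracted from homogenised left ventricle, 200 ng of total RNA was depleted of ribosomal RNA, and libraries were built with a directional kit that keeps strand information. Per the submitters' processing notes, the tools were bcl2fastq 2.19.1.403, which makes read files, and kallisto 0.46.0, which assigns reads to transcripts by pseudoalignment and returns estimated counts. The genome build, the annotation, the handling of strand and any filter on reads are not given in the sources used here. Because reads are assigned to transcripts, the estimated count of a gene with near-identical copies, such as the globins, actins, myosins and nuclear copies of mitochondrial genes, depends on how shared reads were divided, and without a stated strand setting an antisense or overlapping gene may share reads with its partner.

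The authors deposited one table of estimated counts, with 55385 genes in rows and the 8 samples in columns named by sample title. The deposited estimated counts are whole numbers, so rounding them before the tests changed nothing. They are not scaled for library size. Of the gene identifiers, 54487 match GENCODE M21 (GRCm38) with their version and 55144 without it, and 52797 also carry the same symbol there. Symbols are those of the deposited table. Where several identifiers share a symbol, the one with most counts carries it. The position of Stk4 comes from GENCODE M21, which was used here also for transcript lengths.

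Groups were taken from the sample titles. Replicate numbers run from 1 to 4 in both groups, but nothing in the labels says that animals with the same number are paired, so the main comparison used the group alone. The labels number the samples without stating for each that it is a separate animal, so p-values measure the spread between these samples. Comparing the replicates found no pair that agreed within counting noise. The depth was 21193536 to 23809256 counts per library. At this depth and with a biological coefficient of variation of 11.4%, the median standard error of a log2 fold change was 0.111.

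Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 15314 genes and set aside 40071. Library sizes were scaled by TMM factors, and groups were compared with the quasi-likelihood F test (robust fit) with Benjamini-Hochberg adjustment and a threshold of 0.05 over all genes tested. The standard error (SE) of a log2 fold change is the fold change divided by the root of its F statistic. CPM values are counts scaled to a common library size by the TMM factors, given as mean ± SD over n = 4 libraries per group, and a log2 fold change is Mst1-TG over WT ± SE throughout. For genes with few WT counts a ratio of counts with an exact 95% interval is given, which covers counting error only. A rise or fall is named only where the edgeR adjusted p was below 0.05.

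There were 38 gene lists, with 836 different genes of which 798 were tested, fixed with their members before the data were examined. Each needed at least 3 tested members. They cover the Hippo pathway, YAP/TEAD targets, cardiomyocyte stress genes, sarcomere, calcium handling, ion channels, fatty acid oxidation, nuclear and mitochondrial respiratory chain genes, the TCA cycle, mitochondrial regulators, PPAR alpha targets, 6 groups of lipid synthesis and storage genes, glycolysis, matrix, inflammation, interferon response, p53, the integrated stress response, chaperones, antioxidants, cell cycle, immediate early genes and 10 sets of cell type markers. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Counts of changed members are given over all genes tested and adjusted over the list alone. Named genes follow a rule fixed at the same time: Stk4; the 12 largest rises and 12 largest falls among genes that passed, had a mean log2 CPM of at least 1, carried a gene symbol of the ordinary kind and did not overlap between groups; up to 4 members of each list with the smallest p; and a set of 21 heart genes whatever their change. Exceptions are said to be so where they stand. Some genes that the rule selects are left out of the text.

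The test was tried on simulated data before it was run on the counts. In counts drawn from the real means and library sizes (15105 genes tested for Mst1-TG against WT), 84% of 100 genes changed 2-fold and 67.0% of 97 genes changed 1.5-fold were recovered, 5.70% of the calls were false, and 5 of 100 random lists had a camera p below 0.05. The simulation drew each gene independently, changed only 200 genes and built in no difference in library composition. Its error rates therefore do not cover counts in which 42.3% of genes differ, as found here. Independent genes also cannot test the preset correlation of camera.

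Alternatives chosen before the data were examined were DESeq2 size factors, upper quartile factors or library totals as scaling, no filter on low counts or a mean of at least 10 counts, DESeq2 1.42.0, limma-voom, a replicate block, leaving out the 20 most abundant and the mitochondrially encoded genes, stricter thresholds (0.01, or a minimum 1.5-fold change), and leaving out each library in turn. Chosen after seeing the data were 4 lists with members removed and the comparison without WT 4 and Mst1-TG 1 together. The 35 splits of the 8 libraries into 4 and 4 were each fitted in the same way. Differences in a single value per library were tested with an exact permutation test, two-sided, whose smallest p is 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.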

Results

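The data set holds 8 RNA-seq libraries of left ventricle from male C57BL6 mice, 4 from carriers of the Mst1 transgene (Mst1-TG) and 4 from littermate non-transgenic controls (WT). Mst1 is a kinase of the Hippo pathway, which phosphorylates the Lats kinases that in turn restrain the transcriptional coactivators YAP and TAZ. Its mouse gene is Stk4, while the mouse symbol Mst1 belongs to another gene. In the transgenic strain the kinase is expressed from the alpha-myosin heavy chain promoter, which restricts it to cardiomyocytes, and the mice develop dilated cardiomyopathy. The series' design text places these mice at 3 weeks of age, whereas the RNA extraction protocol in the labels says 3 months. The growth protocol names young mice of 3 weeks and adult mice of 5.5 months. The age is given here as the design text states it. The libraries held between 21193536 (WT 4) and 23809256 (WT 1) estimated counts, assigned to 55385 genes, of which 15314 passed the filter on low counts. The question that the design poses is how the left ventricular transcriptome differs between Mst1-TG and WT hearts, with attention to lipid metabolism.

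The libraries differed in how much of their RNA was mitochondrial. Mitochondrially encoded genes took 22.9% ± 1.11 (SD, n = 4) of the counts in WT and 13.6% ± 0.676 (SD, n = 4) in Mst1-TG (exact permutation test, two-sided p = 0.0286, the smallest p that 4 against 4 can give). The TMM scaling factors were 0.906 ± 0.0219 (SD, n = 4) in WT and 1.10 ± 0.0212 (SD, n = 4) in Mst1-TG. Groups separated on the first principal component, which held 62.7% of the variance, while WT 4 lay apart from the other WT libraries on the second, which held 8.89%. Replicates of one group differed from each other by more than counting noise (chi-square per degree of freedom 7.92 to 23.4 over the pairs), so each was counted as a separate sample.

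Stk4 itself was far higher in every Mst1-TG library. Its level was 27.2 ± 1.88 CPM in WT and 1608 ± 130.3 CPM in Mst1-TG (SD, n = 4 each), a 59.0-fold difference (log2 fold change 5.88 ± 0.10 SE, edgeR adjusted p = 8.1e-13). Stk4 (ENSMUSG00000018209.15) lies on chromosome 2 from 164070322 to 164155524 on the forward strand in the GENCODE M21 annotation of GRCm38. Gene-level counts cannot separate transcripts of the transgene from those of the endogenous gene. The labels do not give the species or sequence of the transgene, so how much of it these counts include is unknown, and the 59.0-fold difference need not be its full level. The lowest Mst1-TG library (1449 CPM) lay far above the highest WT library (29.6 CPM), in the direction that the labels give.

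Expression differed widely between the groups. Of 15314 genes tested, 3244 were higher and 3238 lower in Mst1-TG at an edgeR adjusted p below 0.05, together 42.3% of the genes, and 889 of the higher and 705 of the lower genes differed at least 2-fold. In 40.3% of the tested genes the 4 Mst1-TG libraries did not overlap the 4 WT libraries, against 2.86% by chance. The direction of small changes depends on scaling: with library totals as the only scaling the median gene moved from 0.01 to 0.29 on the log2 scale, and 7409 genes were called higher and 1592 lower. Testing against a minimum 1.5-fold change left 894 higher and 848 lower genes.

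Several of the largest rises were in genes that were nearly silent in WT. Mybph, a myosin-binding protein, rose from 5 counts over the 4 WT libraries to 41.7 ± 15.3 CPM in Mst1-TG (SD, n = 4), with a count ratio of 682 (95% counting interval 292 to 2101). Most of these WT counts came from WT 3 (0.190 CPM, against 0.0472 in WT 1 and 0 in WT 2 and WT 4). Counts of Syndig1, a synaptic membrane protein, were higher by a ratio of 190 (73.9 to 698). The membrane mucin Muc15 had a ratio of 123 (41.9 to 599.5), resting on 3 WT counts that all came from WT 4. The serpin Serpinb1c, a member of a family with close copies whose reads may be shared, had a ratio of 62.7 (30.2 to 157). Its WT counts came from WT 3 (0.238 CPM) and WT 2 (0.103 CPM), with 0 in WT 1 and WT 4. Among genes with more WT counts, Shisa3, a modulator of Wnt and FGF signalling, rose from 1.99 ± 0.237 to 91.6 ± 7.93 CPM (log2 fold change 5.52 ± 0.10 SE, edgeR adjusted p = 1.4e-12). The chemokine receptor Cxcr6 rose by 5.50 ± 0.24 (SE), the muscle triad protein Sypl2 by 5.45 ± 0.23, the lectin Chodl by 5.27 ± 0.44 and the exchange factor Ngef by 5.11 ± 0.22 on the log2 scale. Frem1, an extracellular matrix protein, rose by 4.95 ± 0.16.

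The deepest fall among the named genes was in Ces1d, a carboxylesterase that hydrolyses triglyceride and belongs to a cluster of close copies. It went from 34.9 ± 6.2 to 1.77 ± 1.01 CPM (SD, n = 4 each; log2 fold change -4.29 ± 0.32 SE, edgeR adjusted p = 5.6e-06). Ogdhl, a relative of the TCA cycle enzyme oxoglutarate dehydrogenase, went from 164 ± 17.7 to 10.1 ± 2.59 CPM (-4.03 ± 0.17, adjusted p = 7.9e-08). The water channel Aqp4 changed by -4.02 ± 0.27, the muscle fructose bisphosphatase Fbp2 by -3.74 ± 0.17 and the alpha-1A adrenergic receptor Adra1a by -3.46 ± 0.33. Pm20d1, which makes N-acyl amino acids, changed by -3.41 ± 0.26, and the amino acid transporter Slc36a2 by -3.08 ± 0.30. Falls were also called for Myo5c (-2.99 ± 0.37), Tmod4 (-2.97 ± 0.27), the potassium channel Kcnj3 (-2.96 ± 0.20) and the sodium channel Scn4a (-2.94 ± 0.27). Cyp26b1, which degrades retinoic acid, varied between WT libraries (36 ± 34 CPM, against 4.28 ± 1.43 in Mst1-TG). Its change of -3.07 ± 0.87 passed at an edgeR adjusted p of 0.03, but not without any one of the Mst1-TG libraries (-3.10, -2.90, -3.02 and -3.28 without Mst1-TG 1, 2, 3 and 4), without WT 4 (-2.96), with limma-voom (adjusted p = 0.138) or without a filter on low counts (adjusted p = 0.061). Over all the alternatives the change of Cyp26b1 ran from -3.40 to -2.30.

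**Figure D1:**
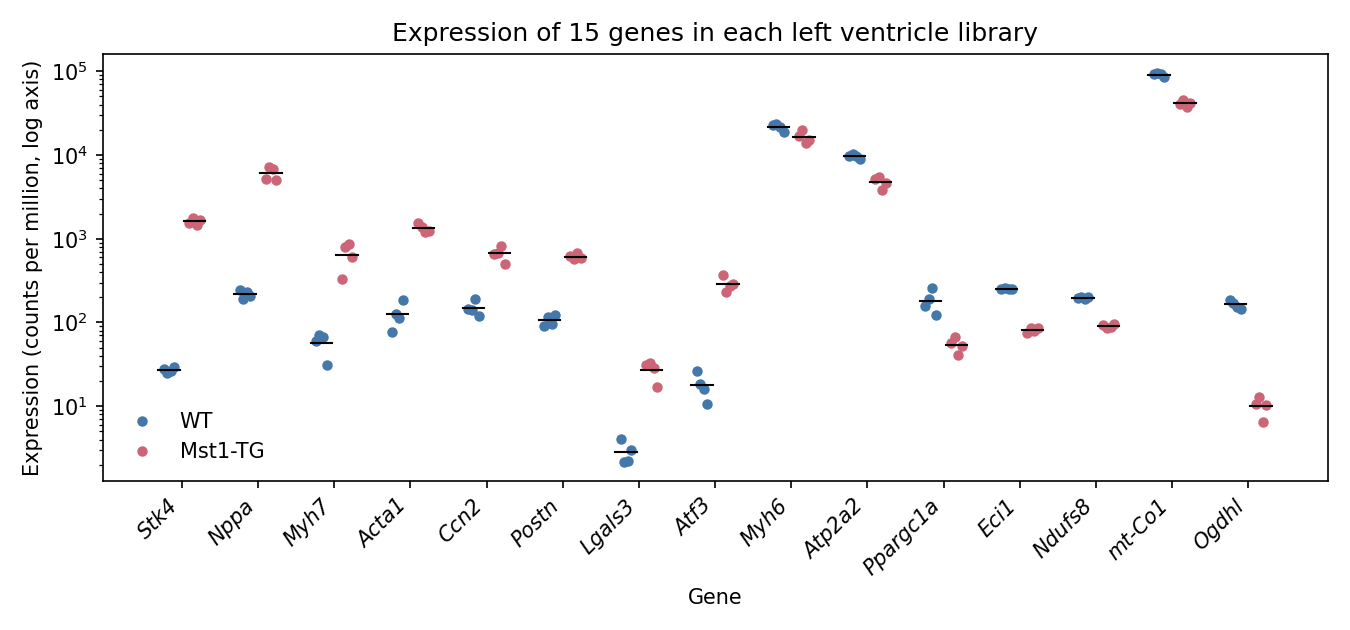
Expression of 15 genes in CPM (log axis), with 1 point per library, WT in blue and Mst1-TG in red, and the group mean as a black line. Stk4, the stress genes, Ccn2, Postn, Lgals3 and Atf3 are higher in all 4 Mst1-TG libraries, and the metabolic genes from Ppargc1a to Ogdhl are lower in all 4, while the groups overlap for Myh6.

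Of 23 measured members of the Hippo pathway, Stk4 among them, 12 rose and the other 11 did not pass (13 higher and 0 lower, adjusted over the list alone), with a median log2 fold change of 0.23. Camera gave an adjusted p of 3.0e-04, and adjusted p = 0.1 with an estimated correlation. The junction-associated adaptors Frmd6 and Amot rose by 0.51 ± 0.08 and 0.61 ± 0.11 (SE), and the upstream kinase Taok3 by 0.49 ± 0.09. Without Stk4 as a member the list's median was 0.22 and its camera adjusted p was 0.096, which did not pass. Target genes of YAP and its TEAD partners rose in 13 of 23 cases and fell in 3 (13 higher and 4 lower, adjusted over the list alone), with a median of 0.27. The camera test of the list gave adjusted p = 4.4e-05, and adjusted p = 0.079 with an estimated correlation. Ccn2, a secreted matricellular protein, rose from 149.6 ± 30.7 to 668 ± 131 CPM (log2 2.16 ± 0.17, edgeR adjusted p = 3.6e-06). Its relative Ccn1 rose by 1.15 ± 0.08, the receptor kinase Axl by 0.94 ± 0.06 and the growth factor Tgfb2 by 1.33 ± 0.07. Ankrd1, a sarcomeric ankyrin-repeat protein, rose by 2.64 ± 0.17. These members are also made by fibroblasts or counted among stress genes. Without Ankrd1 and Tgfb2 the median was 0.23 (camera adjusted p = 0.0033). Ccn1, Ccn2 and Axl stayed in that list, so the value does not separate YAP/TEAD targets from the rise of fibroblast genes.

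Genes that mark a stressed or fetal-like myocardium had the highest median of the 38 lists. Of 15 stress genes 13 rose and the other 2 did not pass (14 higher and 0 lower, adjusted over the list alone), with a median log2 fold change of 2.50. In camera the list had an adjusted p of 5.0e-22 (adjusted p = 0.051 with an estimated correlation). Atrial natriuretic peptide (Nppa) went from 218 ± 24.3 to 6084 ± 1079 CPM (SD, n = 4 each), a 27.8-fold rise, and brain natriuretic peptide (Nppb) from 249 ± 52.9 to 548 ± 59.4 CPM, a 2.20-fold rise (edgeR adjusted p = 3.4e-10 and 4.9e-05). The slow myosin heavy chain Myh7 rose by 3.50 ± 0.41 and skeletal alpha-actin Acta1 by 3.41 ± 0.25 on the log2 scale, each with a near-identical cardiac copy whose reads can be shared. Xirp2, an actin-binding protein of the intercalated disc, rose by 4.30 ± 0.17, and the ubiquitin hydrolase Uchl1 by 2.91 ± 0.07. Gdf15, a stress cytokine, was at 1.85 ± 0.256 CPM in WT and 3.71 ± 2.28 in Mst1-TG and did not pass (1.00 ± 0.43, edgeR adjusted p = 0.088), but passed without Mst1-TG 4 (1.31, adjusted p = 0.0019), with library totals only (0.025), without a count filter (5.5e-04) and with DESeq2 (0.042 in the fit with its own size factors). Immediate early genes, which also respond to handling of the tissue, rose in the same hearts: 8 of 13 members were higher and the other 5 did not pass (8 higher and 0 lower, adjusted over the list alone). Their median was 0.71, and as a list they had a camera adjusted p of 1.2e-04 (adjusted p = 0.171 with an estimated correlation). Egr2 rose by 3.01 ± 0.29, Egr3 by 2.44 ± 0.19, Junb by 1.03 ± 0.09 and Jun by 0.71 ± 0.07.

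Sarcomere genes of the adult ventricle changed less than the stress genes. The list had 9 of 20 members lower and 2 higher (2 higher and 10 lower, adjusted over the list alone), with a median of -0.30 that went to -0.01 with library totals only, which gave 6 higher and 5 lower. For the list camera's adjusted p was 0.0054, and adjusted p = 0.542 with an estimated correlation. Leaving out the 20 most abundant and the mitochondrially encoded genes, several of which are sarcomere genes, ended the call (median -0.13, adjusted p = 0.14). Troponin I (Tnni3) fell from 3197 ± 177 to 1270 ± 135 CPM (log2 -1.33 ± 0.09), the ventricular myosin light chains Myl3 and Myl2 by 0.92 ± 0.08 and 0.90 ± 0.09, and tropomyosin Tpm1 by 0.73 ± 0.08. The adult myosin heavy chain Myh6 was at 21710 ± 2124 CPM in WT and 16450 ± 2603 in Mst1-TG, with overlapping libraries (-0.40 ± 0.12, edgeR adjusted p = 0.014), and with library totals only it did not pass (-0.12, adjusted p = 0.344).

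Calcium-handling genes were lower in 8 of 19 cases and higher in 2 (2 higher and 8 lower, adjusted over the list alone), and the median of -0.22 turned to 0.06 with library totals only, which gave 6 higher and 5 lower. The list's camera adjusted p was 0.015, against adjusted p = 0.387 with an estimated correlation. The sarcoplasmic reticulum calcium pump Atp2a2 fell from 9671 ± 612 to 4774 ± 690.0 CPM (log2 -1.02 ± 0.11, edgeR adjusted p = 5.5e-06). Hrc, a calcium-binding protein of the same compartment, changed by -1.84 ± 0.14, the counter-ion channel Tmem38a by -0.79 ± 0.07 and the dyad protein Jph2 by -0.72 ± 0.08. Ion channels and gap junction genes fell in 14 of 21 cases and the other 7 did not pass (0 higher and 14 lower, adjusted over the list alone). Their median was -0.46, and camera gave an adjusted p of 9.3e-07, and adjusted p = 0.186 with an estimated correlation. Library totals only gave 2 higher and 10 lower, with a median of -0.17. Kcnip2 and Kcnd3, subunits of the channel for the transient outward potassium current, changed by -1.70 ± 0.08 and -1.79 ± 0.18, and Abcc9, the sulphonylurea receptor, by -0.79 ± 0.08.

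Energy metabolism genes fell nearly as a block, in libraries whose mitochondrial share of counts was also lower. All 73 nuclear-encoded subunits of the respiratory chain and ATP synthase that were measured fell (0 higher and 73 lower, adjusted over the list alone), with a median log2 fold change of -1.02. As a list they had a camera adjusted p of 7.3e-66 (adjusted p = 0.079 with an estimated correlation). The complex I subunits Ndufs8, Ndufs4, Ndufa9 and Ndufa8 changed by -1.12 ± 0.06, -1.17 ± 0.07, -1.17 ± 0.07 and -1.06 ± 0.06 (SE). With library totals as the only scaling 70 of the 73 were still called lower, with a median of -0.74. Fatty acid uptake and beta-oxidation genes fell in 27 of 28 cases (0 higher and 27 lower, adjusted over the list alone), with a median of -1.12. Camera gave an adjusted p of 3.2e-35, and adjusted p = 0.079 with an estimated correlation. Eci1, an isomerase for unsaturated acyl-CoA, went from 250.4 ± 4.03 to 81.2 ± 5.14 CPM (log2 -1.63 ± 0.06, edgeR adjusted p = 2.9e-09). The electron transfer flavoprotein subunit Etfb changed by -1.53 ± 0.07, Hadh by -1.57 ± 0.08, Crat by -1.42 ± 0.07, and Cpt1b, which makes the acylcarnitines that enter mitochondria, by -0.80 ± 0.09. TCA cycle and pyruvate dehydrogenase genes fell in 21 of 22 cases (0 higher and 21 lower, adjusted over the list alone; median -1.09, camera adjusted p = 2.7e-27; adjusted p = 0.079 with an estimated correlation), among them Idh3b (-1.30 ± 0.07), Sucla2 (-1.29 ± 0.08), Suclg1 (-1.24 ± 0.08) and the pyruvate carrier Mpc2 (-1.15 ± 0.07). Mitochondrially encoded protein genes fell in 11 of 13 cases (0 higher and 12 lower, adjusted over the list alone). Their median was -0.97, and the camera test of the list gave adjusted p = 8.4e-11, and adjusted p = 0.171 with an estimated correlation. mt-Co1, the most abundant of them, went from 90850 ± 4249 to 41350 ± 3295 CPM, and mt-Co3, mt-Nd2 and mt-Atp6 changed by -1.13 ± 0.08, -1.08 ± 0.08 and -0.97 ± 0.08. Nuclear copies of mitochondrial genes can take some of these reads.

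Regulators of these genes were lower as well. Of 22 genes for mitochondrial biogenesis and dynamics 13 fell and the other 9 did not pass (0 higher and 16 lower, adjusted over the list alone). Their median was -0.54, and in camera the list had an adjusted p of 1.1e-05 (adjusted p = 0.171 with an estimated correlation). The coactivator Ppargc1a went from 183 ± 58 to 53.9 ± 10.8 CPM (log2 -1.76 ± 0.25, edgeR adjusted p = 6.9e-04), and its partner receptors Ppara and Esrra changed by -1.35 ± 0.19 and -0.61 ± 0.07. Tfam, which packages mitochondrial DNA, changed by -0.47 ± 0.07, the fusion proteins Mfn1 and Opa1 by -0.84 ± 0.08 and -0.70 ± 0.07, and the mitophagy kinase Pink1 by -0.80 ± 0.09. PPAR alpha target genes fell in 15 of 20 cases and the other 5 did not pass (0 higher and 15 lower, adjusted over the list alone). Their median was -0.83, and for the list camera's adjusted p was 2.6e-08, and adjusted p = 0.171 with an estimated correlation. The fatty acid hydroxylase Cyp4b1 changed by -1.37 ± 0.12, Acadm by -1.25 ± 0.09 and the carnitine carrier Slc25a20 by -1.04 ± 0.10. Pdk4, the kinase that restrains pyruvate dehydrogenase, did not pass (904 ± 491 CPM in WT and 692 ± 128 in Mst1-TG; -0.39 ± 0.48, edgeR adjusted p = 0.572), but without WT 1 it did (-0.70, adjusted p = 0.014).

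Lipid genes other than those of oxidation moved in several directions. Genes for triglyceride synthesis, lipolysis and lipid droplets fell in 18 of 28 cases and rose in 2 (2 higher and 18 lower, adjusted over the list alone), with a median of -0.65. The camera test of the list gave adjusted p = 1.6e-06, and adjusted p = 0.11 with an estimated correlation. Dgat2, which makes the last step of triglyceride synthesis, changed by -1.85 ± 0.13, the lipid droplet proteins Fitm1, Fitm2 and Plin3 by -1.55 ± 0.12, -1.03 ± 0.09 and -0.92 ± 0.09. Ether lipid and peroxisome genes fell in 15 of 24 cases and rose in 2 (2 higher and 16 lower, adjusted over the list alone). Their median was -0.43, and the list's camera adjusted p was 8.7e-05, against adjusted p = 0.133 with an estimated correlation. Library totals only gave 6 higher and 11 lower, with a median of -0.14. Phyh, of peroxisomal alpha-oxidation, changed by -1.23 ± 0.08, Gnpat, the first enzyme of plasmalogen synthesis, by -0.84 ± 0.07, and Pex11a and Amacr by -1.42 ± 0.15 and -0.81 ± 0.08. Phospholipid and cardiolipin genes were split, with 12 of 37 lower and 7 higher (7 higher and 12 lower, adjusted over the list alone), and their median of -0.14 turned to 0.15 with library totals only, which gave 15 higher and 3 lower (camera adjusted p = 0.554; fry adjusted p = 0.002). Chpt1 and Pcyt2, of phosphatidylcholine and phosphatidylethanolamine synthesis, changed by -0.99 ± 0.08 and -0.81 ± 0.08, while the phospholipase Pla2g4a rose by 1.96 ± 0.13 and the acyltransferase Mboat2 by 1.24 ± 0.12. Sphingolipid genes rose in 15 of 35 cases and fell in 3 (16 higher and 5 lower, adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.094; fry adjusted p = 3.4e-04; camera adjusted p = 0.025 with library totals only and 0.018 without a count filter). Library totals only gave 25 higher and 1 lower in the sphingolipid list, with a median of 0.42. The ceramide synthase Cers6 rose by 1.03 ± 0.10 and sphingosine kinase Sphk1 by 1.59 ± 0.20, and acid sphingomyelinase Smpd1 changed by -0.67 ± 0.06.

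Of 29 cholesterol genes 4 rose and 3 fell (1 and 3, adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.845). With library totals only 14 were higher and 1 lower. The squalene synthase Fdft1 changed by -1.43 ± 0.15 and the cholesterol acyltransferase Soat1 by 0.92 ± 0.11. Fatty acid synthesis, elongation and desaturation genes rose in 10 of 27 cases and fell in 7 (12 higher and 9 lower, adjusted over the list alone), with a median of 0.22 but a mean of -0.07 and camera's direction down (adjusted p = 0.845). The falls included Tecr (-1.25 ± 0.09), the mitochondrial acetyl-CoA carboxylase Acacb (-1.09 ± 0.10), malic enzyme Me1 (-0.96 ± 0.10) and Acsl6 (-2.95 ± 0.32). Library totals only gave 18 higher and 6 lower in the fatty acid synthesis list, with a median of 0.51. Glycolysis genes were lower in 11 of 23 cases and higher in 3 (4 higher and 11 lower, adjusted over the list alone), with a median of -0.17 that turned to 0.12 with library totals only, which gave 11 higher and 9 lower. In camera the list had an adjusted p of 0.049 (adjusted p = 0.452 with an estimated correlation). That call was lost without Mst1-TG 1 (median -0.13, adjusted p = 0.113), Mst1-TG 4 (-0.17, 0.052), WT 1 (-0.13, 0.064) or WT 2 (-0.19, 0.067), and with library totals only (0.12, 0.133). The insulin-responsive glucose transporter Slc2a4 changed by -1.16 ± 0.09, muscle enolase Eno3 by -1.21 ± 0.10 and heart lactate dehydrogenase Ldhb by -1.20 ± 0.07, whereas the ubiquitous glucose transporter Slc2a1 rose from 9.77 ± 2.14 to 36.3 ± 4.05 CPM (1.89 ± 0.14).

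Matrix genes rose almost without exception. Of 35 matrix and fibrosis genes 34 rose (35 higher and 0 lower, adjusted over the list alone), with a median of 1.37. For the list camera's adjusted p was 4.2e-38, and adjusted p = 0.079 with an estimated correlation. Periostin (Postn), made by activated fibroblasts, went from 107 ± 15.3 to 613 ± 40.1 CPM (log2 2.52 ± 0.10, edgeR adjusted p = 3.3e-09), and galectin-3 (Lgals3) from 2.87 ± 0.882 to 27.3 ± 7.07 CPM (3.24 ± 0.26). Among collagens Col8a1 rose by 2.98 ± 0.09, Col1a1 by 1.61 ± 0.16, Col5a2 by 1.46 ± 0.08 and Col3a1 by 0.87 ± 0.15, and the gelatinase Mmp2 by 1.46 ± 0.08. Fibroblast markers rose in 11 of 12 cases (11 higher and 0 lower, adjusted over the list alone; median 1.13, camera adjusted p = 8.4e-11; adjusted p = 0.079 with an estimated correlation), with Mfap5 up by 2.25 ± 0.12, Meox1 by 2.05 ± 0.13, decorin (Dcn) by 1.21 ± 0.09 and Pdgfra by 1.13 ± 0.08. Col14a1 is on both lists.

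The endothelial, pericyte, macrophage, lymphocyte and adipocyte lists did not pass camera's threshold. Endothelial markers were lower in 6 of 14 cases and higher in 1 (1 higher and 6 lower, adjusted over the list alone), and the median of -0.27 turned to 0.02 with library totals only, which gave 1 higher and 1 lower (camera adjusted p = 0.124, 0.018 with a median of -0.36 without Mst1-TG 3, and 0.021 with -0.26 without a count filter). Robo4 changed by -0.76 ± 0.07 and von Willebrand factor (Vwf) by 0.86 ± 0.16. Pericyte and smooth muscle markers fell in 4 of 11 cases and rose in 2 (3 higher and 5 lower, adjusted over the list alone; median -0.26; 0.02 with library totals only, which gave 5 higher and 2 lower; camera adjusted p = 0.845), with Cspg4 up by 1.37 ± 0.06 and vitronectin (Vtn) and smooth muscle actin (Acta2) changed by -1.64 ± 0.12 and -1.41 ± 0.25. Macrophage markers had a median of 0.16 over 16 genes (camera adjusted p = 0.561), with Ccr2 higher (0.86 ± 0.19) and Cd163 lower (-0.55 ± 0.14; -0.27, adjusted p = 0.108 with library totals only) and the other 14 short of the threshold (1 higher and 1 lower, adjusted over the list alone). With library totals only, 9 markers were higher and 0 lower, with a median of 0.44. Of the 14, Mrc1 passed as higher without Mst1-TG 1 (0.39, adjusted p = 0.01), with library totals only (0.58, 0.0034), with upper quartile factors (0.34, 0.0499) and without a count filter (0.30, 0.0011). Fcgr1 did so without Mst1-TG 2 (0.79, 0.012), with library totals only (0.88, 0.015) and without a count filter (0.60, 0.018). Lymphocyte markers had a median of -0.26 over 8 genes, 0.03 with library totals only (camera adjusted p = 0.49), and Cd79b fell (-1.16 ± 0.34; list count 0 higher and 2 lower, adjusted over the list alone), but not without WT 4 (-0.84, adjusted p = 0.058), while Cd79a, short of the threshold (adjusted p = 0.087), passed without WT 1 (-1.09, 0.0499) and without a count filter (-0.89, 0.031). Of 4 measured adipocyte markers not one passed in edgeR, with adjusted p of 0.116 (Trarg1), 0.627 (Pck1), 0.673 (Cfd) and 0.716 (Car3), the list median being -0.57 (camera adjusted p = 0.806); Trarg1 alone passed when WT 1 was left out (-0.52, adjusted p = 0.036) and with replicate number as a block (-0.39, 0.044).

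Blood, nerve, atrial and epicardial markers varied by gene. The platelet gene Ppbp was the 1 of 10 blood markers that passed (2.10 ± 0.42; 1 higher and 0 lower, adjusted over the list alone; list median -0.12, 0.17 with library totals only; camera adjusted p = 0.892), and alpha-globin Hba-a1, which has a near-identical copy, was at -0.79 ± 0.33 (edgeR adjusted p = 0.088; -0.98 and 0.027 without WT 2; -0.78 and 0.039 with replicate number as a block). Schwann cell and neuron markers rose in 3 of 9 cases and fell in 2 (3 higher and 2 lower, adjusted over the list alone), with a median of -0.01 but a mean of 0.08 and camera's direction up (adjusted p = 0.125, and 0.035 with a median of 0.25 without a count filter; fry adjusted p = 8.2e-04). That direction rested on Uchl1, also a stress gene and the largest riser of the list: without it the median was -0.05 and the direction down in camera (adjusted p = 0.563) and fry (0.093). Cdh19 rose by 0.77 ± 0.18 and Dbh, which makes noradrenaline, changed by -2.27 ± 0.18. Atrial markers rose in 3 of 8 cases and fell in 3 (5 higher and 3 lower, adjusted over the list alone; 5 higher and 1 lower with library totals only). Their median was 0.24, and as a list they had a camera adjusted p of 2.9e-04 (adjusted p = 0.171 with an estimated correlation). Nppa, Dkk3 (1.43 ± 0.10) and Pam (1.11 ± 0.08) rose, whereas sarcolipin (Sln), a small atrial calcium pump regulator, was lower (-1.28 ± 0.35, edgeR adjusted p = 0.016, 0.052 with -1.28 without Mst1-TG 3, and 0.059 with -1.27 without a count filter). Without Nppa the atrial list's median was 0.21 and its camera adjusted p 0.136. Epicardial markers rose in 4 of 9 cases and the other 5 did not pass (4 higher and 0 lower, adjusted over the list alone; median 0.73, camera adjusted p = 0.012; adjusted p = 0.186 with an estimated correlation; 0.112 and a median of 1.01 with library totals only). The rises included the keratins Krt18 (3.59 ± 0.22), Krt8 (3.03 ± 0.30) and Krt19 (1.63 ± 0.33), which injured cells of several types also make.

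Stress programs rose in part. Integrated stress response genes rose in 14 of 26 cases and fell in 1 (15 higher and 1 lower, adjusted over the list alone). Their median was 0.41, and camera gave an adjusted p of 0.0038, and adjusted p = 0.171 with an estimated correlation. The transcription factor Atf3, which is also an early-response gene, went from 17.9 ± 6.6 to 291 ± 57.9 CPM (log2 4.02 ± 0.28, edgeR adjusted p = 9.9e-06). Nupr1 rose by 1.55 ± 0.15, the serine synthesis enzyme Psat1 by 1.43 ± 0.12 and the amino acid transporter Slc7a5 by 1.10 ± 0.12, while the 1 fall was Shmt2 (-0.43 ± 0.07), named after its value was seen. Fgf21 had 2 counts over the WT libraries and 24 over the Mst1-TG libraries and was too low to test. Genes of p53 and apoptosis rose in 14 of 25 cases and fell in 5 (14 higher and 5 lower, adjusted over the list alone; median 0.37, camera adjusted p = 0.012; adjusted p = 0.186 with an estimated correlation), with Phlda3 up by 1.53 ± 0.08, the survival gene Bcl2 by 1.23 ± 0.08 and Zmat3 by 0.93 ± 0.10. Endoplasmic reticulum chaperones were lower in 5 of 18 cases and higher in 1 (1 higher and 5 lower, adjusted over the list alone), with a median of -0.19 that turned to 0.09 with library totals only, which gave 8 higher and 2 lower (camera adjusted p = 0.138; 0.034 and a median of -0.27 without Mst1-TG 1; 0.026 and -0.20 without a count filter). Herpud1 changed by -0.97 ± 0.08 and the chaperone Hspa5 by -0.72 ± 0.11, and Dnajb11 was the 1 that rose (0.22 ± 0.06). Antioxidant genes fell in 12 of 24 cases and rose in 5 (5 higher and 12 lower, adjusted over the list alone; median -0.28; 0.001 with library totals only, which gave 7 higher and 9 lower; camera adjusted p = 0.0058; adjusted p = 0.296 with an estimated correlation). The members that moved most clearly included enzymes of mitochondria, Sod2 (-1.24 ± 0.08), Prdx5 (-1.07 ± 0.07) and Prdx3 (-0.91 ± 0.07), and the glutathione transferase Gsta4 (-1.60 ± 0.08).

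Cell cycle genes rose in 18 of 34 cases and fell in 1 (19 higher and 1 lower, adjusted over the list alone), with a median of 0.67. The list's camera adjusted p was 0.012, against adjusted p = 0.725 with an estimated correlation. The call was lost without Mst1-TG 1 (median 0.57, adjusted p = 0.055), with library totals only (0.95, 0.203) and in fry (adjusted p = 0.062). Cenpe, a kinetochore motor, went from 0.633 ± 0.235 to 2.18 ± 0.233 CPM, Ube2c rose by 1.03 ± 0.23 and Anln by 1.01 ± 0.24, while Cenpf was the 1 that fell (-1.07 ± 0.18). Inflammation genes rose in 7 of 20 cases and fell in 2 (7 higher and 2 lower, adjusted over the list alone; median 0.37, camera adjusted p = 0.144, and 0.037 without a count filter). Library totals only gave 12 higher and 0 lower in the inflammation list, with a median of 0.65. The receptor Tlr4 rose by 0.99 ± 0.11 and the chemokines Cxcl10, Ccl12 and Cx3cl1 by 2.46 ± 0.41, 1.60 ± 0.38 and 0.52 ± 0.14. Interferon response genes had a median near 0 over 24 genes, 0.29 with library totals only, which gave 4 higher and 2 lower (camera adjusted p = 0.806), with Rsad2 (-0.82 ± 0.14) and Cmpk2 (-0.72 ± 0.13) lower (0 higher and 2 lower, adjusted over the list alone). Zbp1 was the 1 called higher (1.31 ± 0.49, edgeR adjusted p = 0.046), a call lost without Mst1-TG 3 (0.89), Mst1-TG 4 (1.33), WT 1 (1.35), WT 2 (0.98) or WT 3 (1.39) and with limma-voom (adjusted p = 0.054). Ifit2 did not pass (0.38 ± 0.16, edgeR adjusted p = 0.074), but passed without Mst1-TG 2 (0.46, adjusted p = 0.039), without WT 4 (0.52, 0.012), with library totals only (0.66, 0.0066), with upper quartile factors (0.43, 0.046), without a count filter (0.39, 0.001) and with replicate number as a block (0.38, 0.017).

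**Figure D2:**
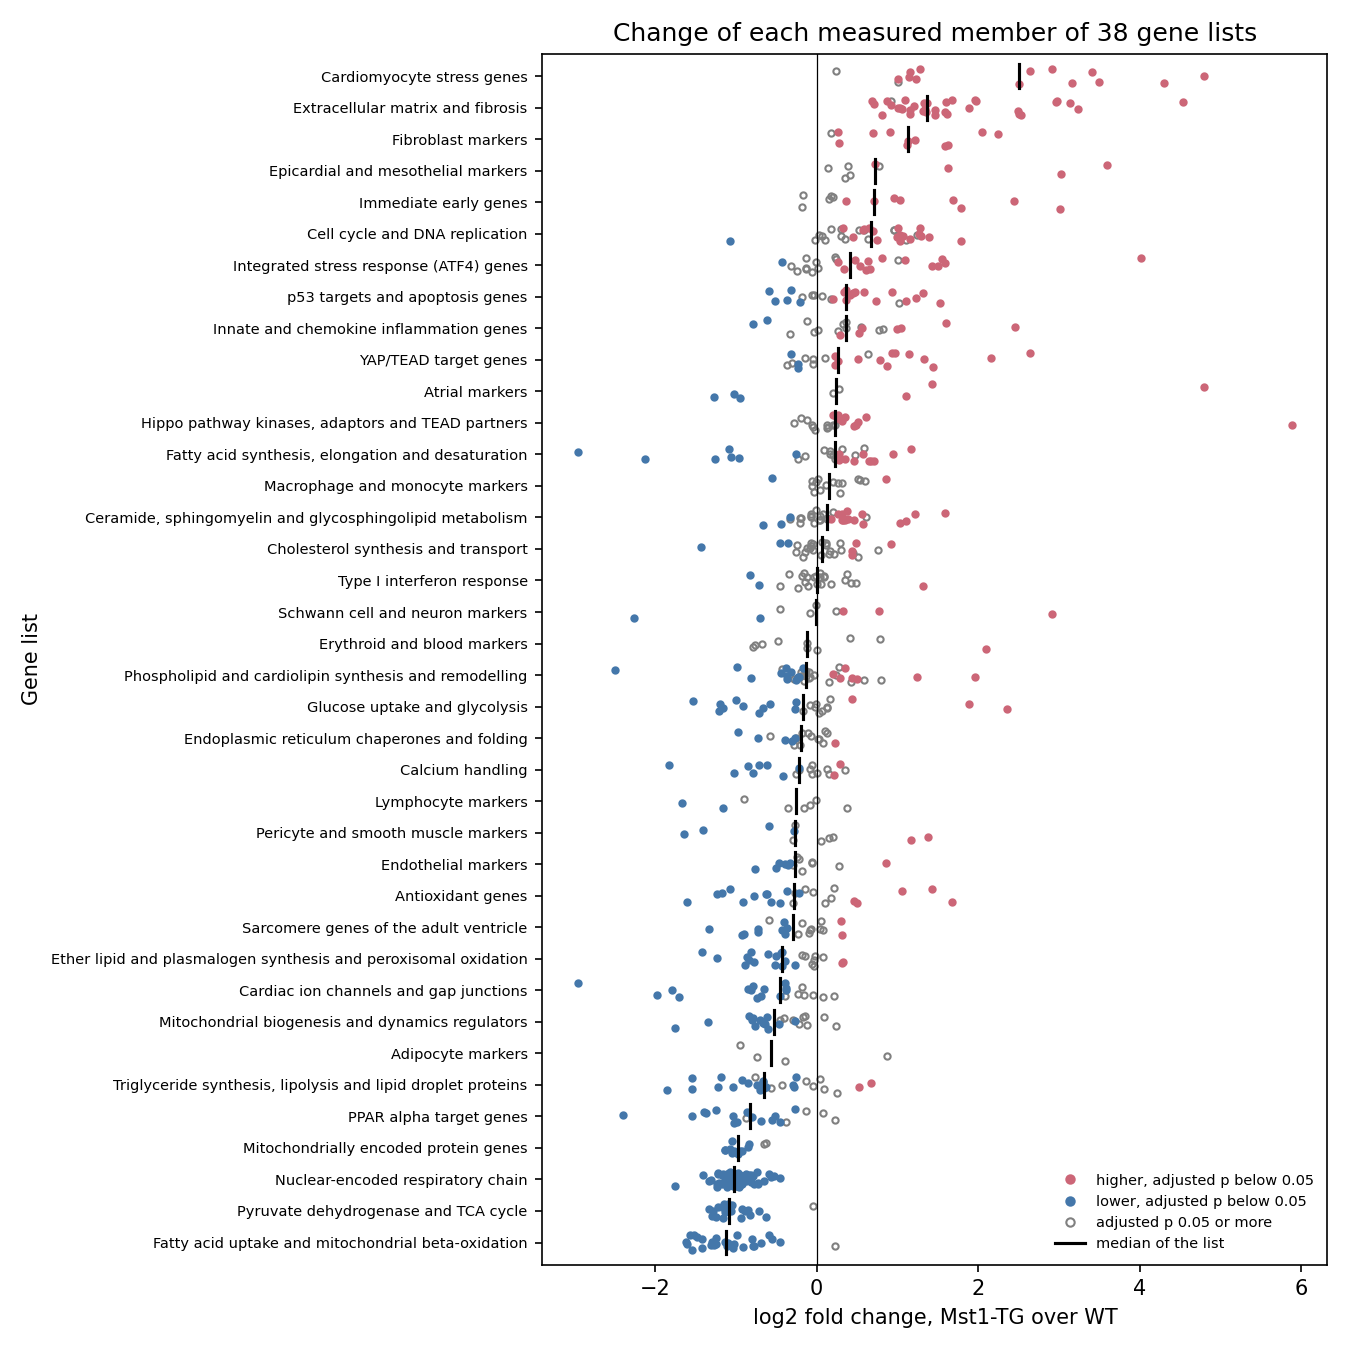
Log2 fold change of Mst1-TG over WT (horizontal axis) for each measured member of 38 gene lists (vertical axis, sorted by median), with 1 point per gene, red or blue where the edgeR adjusted p was below 0.05 and open grey where it was not, and the list's median as a black line. Medians run from -1.12 for beta-oxidation to 2.50 for the stress genes; with library totals only, the medians of the calcium handling, glycolysis, antioxidant (0.001), phospholipid, chaperone, endothelial, pericyte, lymphocyte, erythroid and Schwann cell lists turn positive.

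By camera with a preset correlation of 0.01, 11 of the 38 lists were higher and 13 lower. With the correlation estimated from the libraries not one passed in camera (smallest adjusted p = 0.0506), 10 had an unadjusted p below 0.05, and fry, which asks only whether a list's genes move one way, called 12 higher and 14 lower. The edgeR call of each single member does not depend on that correlation, but correlated members tend to pass or fail together. The estimate was 0.50 for the nuclear-encoded respiratory chain list, so its 73 lower members are not 73 separate findings.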

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

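All tests of the patterns below were chosen after the pattern was seen, except the matched random lists and the splits of the libraries, whose predictions were written before their results were seen. The list levels and the ratios between lists use values already given above. Their permutation p-values restate those changes and are no separate evidence. Over 452 groups of 4 values (named genes, library totals, mitochondrial share and list means), 29 had 1 library far from the other 3, or 6.42%, where chance gives about 1 in 20, and each library had between 3 and 5 of them.

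The number of changed genes was compared with other divisions of the same libraries. Of the 35 splits into 4 and 4, only 1, the real one, gave as many as its 6482 genes, and the highest of the others gave 1 gene. Every other split mixes the groups and so puts the group difference into the spread within groups, which leaves few genes to call. The real count was thus the largest of 35, and the splits cannot exclude chance beyond that. For the number of lists past camera's threshold the real split was not the largest: 7 of the 35 splits, the real one included, gave at least its 24 lists, and the highest of the others gave 25. This share met the prediction written beforehand for a division by chance, so the splits do not set the number of lists apart from chance. The 6 others all took 3 of 4 libraries from one group, as 16 of the 34 do. Splits with 2 of each group called at most 1 gene but gave up to 14 lists. Camera with the preset correlation can thus call lists where the split holds no difference between Mst1-TG and WT.

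Nuclear-encoded respiratory chain genes were lower in Mst1-TG in all 73 cases, with a median of -1.02. A few genes taking more of the counts would lower the other genes of a library alike. The 20 most abundant genes took less of the counts in Mst1-TG (18.8% to 21.2%) than in WT (28% to 30.9%), which is the opposite direction. The mean log2 level of the list relative to the median tested gene, which such a common factor cannot change, differed by -1.03 between Mst1-TG and WT (4.66 ± 0.06 in WT and 3.62 ± 0.09 in Mst1-TG, SD, n = 4 each; exact permutation p = 0.0286). With library totals as the only scaling the median was -0.74. Short transcripts do not account for the fall either: 10000 random lists matched on transcript length and expression had medians no lower than -0.30, and the 79 cytosolic ribosomal protein genes, whose transcripts are as short (median 632 bases, against 635), had a median of -0.01. With sarcomere expression per cell unchanged, a lower share of cardiomyocytes would lower sarcomere genes at least as much. The mean log2 ratio of sarcomere to respiratory chain genes was higher in Mst1-TG by 0.67 (2.28 ± 0.05 in WT and 2.95 ± 0.12 in Mst1-TG, SD, n = 4 each, exact permutation p = 0.0286). On that assumption a lower share is not the whole cause. The sarcomere list itself fell (median -0.30), so a part is not excluded, and expression per cell was not measured. Lower expression of these genes within cardiomyocytes is a hypothesis that stays open with any difference in age or maturity, which was not tested.

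Matrix and fibroblast genes were higher in Mst1-TG. If a loss of cardiomyocytes raised every other cell type, endothelial markers would rise with fibroblast markers, but the mean log2 ratio of fibroblast to endothelial markers was higher in Mst1-TG by 1.31 (-1.97 ± 0.14 in WT and -0.66 ± 0.26 in Mst1-TG, SD, n = 4 each; exact permutation p = 0.0286). More fibroblasts of unchanged expression would raise their markers alike if each marker were exclusive to fibroblasts and even among them. The log2 fold changes of the 12 markers had an SD of 0.69, against a mean SE of 0.12. That SE covers the spread between libraries only, so markers shared with other cells or uneven among fibroblasts are not excluded. A larger number of fibroblasts together with a change in their expression may account for both, and the data cannot divide the 2 parts.

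WT 1 stood apart from the other WT libraries in Plin3 (130.4 CPM, the other 3 at 106 to 108), Fdft1 (33.1 CPM, the other 3 at 25.1 to 25.9) and Cx3cl1 (7.51 CPM, the other 3 at 11.2 to 11.6). In WT 2 the genes that did so were Eci1 (256 CPM, the other 3 at 248 to 249), Ndufs4 (164 CPM, the other 3 at 149 to 151), Sod2 (617 CPM, the other 3 at 548 to 555) and Kcnj8 (72.8 CPM, the other 3 at 88.6 to 90.5). WT 3 did so in Ccn1 (56 CPM, the other 3 at 48.1 to 48.7), Cd163 (25.1 CPM, the other 3 at 21 to 21.1) and Ppbp (1.43 CPM, the other 3 at 0.454 to 0.569). WT 4 did so in Muc15 (0.151 CPM, the other 3 at 0), Ccdc80 (149 CPM, the other 3 at 122 to 126), Cd79a (3.23 CPM, the other 3 at 0.944 to 1.33) and Car3 (13.8 CPM, the other 3 at 0.618 to 2.03). Among Mst1-TG libraries, Mst1-TG 1 was far from the rest in Mybph (64.6 CPM, the other 3 at 32.1 to 35.9), Frmd6 (109 CPM, the other 3 at 88.4 to 91.5), Cxcl10 (3.49 CPM, the other 3 at 1.47 to 1.75), Car3 (8.71 CPM, the other 3 at 0.125 to 0.815) and Egr3 (33.7 CPM, the other 3 at 19.7 to 20.8). Mst1-TG 2 was so in Pink1 (385 CPM, the other 3 at 302 to 314) and Cmpk2 (10.8 CPM, the other 3 at 15 to 15.6). In Mst1-TG 3 these were Sucla2 (203 CPM, the other 3 at 237 to 240.4) and Ccr2 (4.81 CPM, the other 3 at 3.15 to 3.24). Mst1-TG 4 differed in Tgfb2 (32.4 CPM, the other 3 at 36.6 to 37.2), Ndufa8 (145 CPM, the other 3 at 131 to 132) and Mmp2 (571 CPM, the other 3 at 638 to 649.6). The mean log2 CPM of the pyruvate dehydrogenase and TCA cycle list was 7.78 in Mst1-TG 3, with the other 3 libraries of its group at 7.98 to 8.01. The mean log2 CPM of the antioxidant genes list was 5.93 in Mst1-TG 2, with the other 3 libraries of its group at 5.71 to 5.73. The mean log2 CPM of the erythroid and blood markers list was 5.69 in Mst1-TG 3, with the other 3 libraries of its group at 6.30 to 6.37.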

How the results depend on the processing

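Most results held their direction and side of the threshold. The count of genes moved by over 1.5 times only with library totals as scaling (7409 higher and 1592 lower, with 4836 of the 6482 genes still called) and with a minimum 1.5-fold change (894 higher and 848 lower, as a stricter test must). The shift with library totals came from leaving out the TMM factors (0.906 in WT and 1.10 in Mst1-TG), which moved genes nearly alike. The median gene went from 0.008 to 0.293 on the log2 scale. Relative to it, the calcium handling median was -0.228 with TMM and -0.229 with library totals. Which scaling is nearer to the true levels was not tested. Elsewhere, from DESeq2 and limma-voom to leaving out any library, between 5687 and 6920 genes were called, except at an adjusted p of 0.01 (2254 higher and 2386 lower). Without WT 4 and Mst1-TG 1 together, a choice made after seeing the data, 3062 were higher and 3085 lower. With replicate number as a block, 3064 were higher and 3123 lower. The numbers showed no pairing: correlations of same-numbered libraries after removing group means were -0.14, 0.08, 0.02 and -0.02, and 1 of 4 Mst1-TG libraries was closest to its own number.

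Lists past camera's threshold numbered 0 higher and 0 lower with an estimated correlation, and the cause was not tested. The size of the estimate is not all of it. The YAP/TEAD list had an estimate of 0.0185, near the preset 0.01, but its camera adjusted p still went from 4.4e-05 to 0.079. With the estimated correlation 10 lists had an unadjusted camera p below 0.05, and fry called 12 higher and 14 lower. With library totals the medians of lists that had passed turned positive for calcium handling (0.064), glycolysis (0.115) and antioxidants (0.001). The direction of a test changed with some settings for lists that had not passed camera and genes that had not passed edgeR. The Schwann cell and neuron list, called higher by fry, turned down without Uchl1, a choice made after seeing the data (median -0.049; adjusted p = 0.563 in camera and 0.093 in fry). Cholesterol genes had a median of 0.35 with library totals (camera's direction down) and, leaving out 1 library at a time, from -0.049 to 0.14. The pericyte list's median was -0.26 in fry, with fry's direction up, and -0.33 to -0.13 over the left-out libraries. Leaving out each library in turn, the median ran from -0.23 to 0.12 for interferon genes, -0.25 to 0.12 for blood markers and 0.17 to 0.29 for fatty acid synthesis, with camera's direction turned in at least 1 case each. Pck1 was at -0.78 in limma-voom and from -0.55 to 1.37 over the left-out libraries. Cfd ran from -2.95 without Mst1-TG 1 to 0.73 without WT 4, and Car3 from -2.93 to 1.03 with the same libraries left out. The cause of these reversals was not tested. Depth limits genes near the filter, such as Fgf21 with 2 counts in WT and 24 in Mst1-TG.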

Other observations

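Both tests of this part were chosen after values of some of the genes had been seen, and the 21 pairs of isoforms were listed from general knowledge of muscle genes at that stage, so the genes named here fall outside the rule for named genes. In each pair 1 gene was taken as the form of adult heart or striated muscle and its partner as the other form, which is a rough division and least certain for Ogdhl and Ogdh. The muscle form was lower at an edgeR adjusted p below 0.05 in 20 of 21 pairs, with a median log2 fold change of -1.18, and the partner was higher in 7, lower in 5 and had a median of 0.13. Creatine kinase M (Ckm) changed by -1.55 ± 0.11 (SE) and its brain form Ckb by 0.77 ± 0.07. Ribosomal protein Rpl3l, made only in striated muscle, changed by -2.74 ± 0.15 and Rpl3 by 0.34 ± 0.08, and for elongation factor 1A the values were -0.68 ± 0.10 (Eef1a2) and 0.75 ± 0.10 (Eef1a1). Troponin I went from the adult toward the slow skeletal and fetal form, with Tnni3 at -1.33 ± 0.09 and Tnni1 at 3.14 ± 0.20. The ratio of muscle to partner form was lower in Mst1-TG in 21 of 21 pairs, without overlap between the groups in 20, but several of these genes had been seen to change, and 40.3% of all tested genes did not overlap either. Reads of close copies within a pair can be shared, and ratios within a library do not depend on its scaling.

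A hypothesis is that Mst1-TG hearts shifted from muscle to ubiquitous isoforms beyond the genes of the fixed lists. Over the 7 pairs with neither gene on a list or among the named genes, the mean log2 ratio of muscle to partner form went from 1.18 ± 0.07 in WT to -0.33 ± 0.21 in Mst1-TG (SD, n = 4 each), a difference of -1.50 (exact permutation p = 0.0286, the smallest possible), as the hypothesis needs. A fall of the muscle form alone also lowers this ratio. Among the partners Ckb (0.77), Eef1a1 (0.75) and Rpl3 (0.34) rose, while Slc25a5 (-0.28) and Pygb (-0.65) fell. Phkg2 (0.04) and Phka2 (-0.05) did not pass. The ratio therefore does not show a rise of the ubiquitous forms as a set. A lower share of cardiomyocytes may be a candidate explanation. With expression per cell unchanged, it would lower sarcomere genes as much as the muscle isoforms. The mean log2 ratio of sarcomere genes to the muscle isoforms of all 21 pairs was higher in Mst1-TG by 1.04 (1.60 ± 0.05 in WT and 2.65 ± 0.07 in Mst1-TG, exact permutation p = 0.0286). Tnni3 and Myh6, both lower in Mst1-TG, were counted there with the muscle isoforms and not with the sarcomere genes. Falls of many of these isoforms had been seen before, so this p restates them. Expression per cell was not measured, and a part played by a lower share is not excluded. Whether the fall in the ratio follows delayed maturation at this age or disease was not tested.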
